A study of Mus musculus with 2 samples.

How the data were processed

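Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase cuts and tags open DNA, on nuclei from mouse heart. There were 2 libraries, 1 from floxed Ythdc1 control mice and 1 from mice with a cardiac deletion of Ythdc1, both 15 days of age. Group membership came from the genotype label of each sample. With 1 library per genotype there was no spread between animals to test against, and no p-value was computed. How many animals went into each library, and whether a library was pooled, is not given in the sources used here.

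The submitters' processing notes name BWA, MACS2 and the mouse build GRCm38.p6, without versions. Read filters, duplicate removal, the shift of reads for the Tn5 offset, and whether reads, fragments or cuts were counted are not given in the sources used here. The authors deposited a table of 58076 peaks merged over both libraries, with a mark for the library in which each was called. The deposited counts are whole numbers per merged peak, not normalized, per the file headers and the values. The authors' RPM values were checked against the counts and equal (count + 1) times 1 constant per library, 0.01965 in the control and 0.01822 in the knockout. These constants imply library totals larger than the sums over peaks. The authors' fold enrichment, a ratio, follows (count + 1) per base of peak within 0.256%, with no input library. The deposited log2 fold change equals the log2 ratio of the authors' RPM values in each row. Coordinates are those of the deposited table, with starts as it gives them. Feature classes are the authors' annotation, with a promoter being a peak within 1 kb of a transcription start site, and intergenic including the class downstream of genes.

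The counts in peaks were 6755590 in the control and 6466537 in the knockout, 13.3% and 11.8% of the implied totals. The median peak held 65 counts in the control and 60 in the knockout. For each peak the log2 ratio of knockout to control was taken from CPM over the table's peaks, with 0.5 counts added per library. A 2-fold difference was a fixed rule of size, not a test. Exact (Clopper-Pearson) 95% intervals of each ratio cover counting error only. The interval given for a share of higher peaks is also exact, and treats peaks as independent draws. As a second gauge of counting error, 100 binomial draws were made with every peak at the same ratio. This gauge holds no variation between animals, dissections or library preparations. Peaks called in 1 library alone are selected for a high count in that library, so the 2-fold counts depend on peak calling.

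The table gives Ensembl gene identifiers without symbols, and the RefSeq gene table used here, of the same build, shares no identifier with it. Symbols were therefore matched by position. An identifier took the symbol of a RefSeq gene where the overlap of their spans over their union was at least 0.5 and at least 2 times that of the next candidate, or where both ends lay within 1 kb. Identifiers with gene ontology terms (GO) that lay at least 95% inside a single protein-coding gene took its symbol if no other identifier had it. Of 24480 identifiers, 18249 (74.5%) were matched, including 96.3% of those with GO terms, and 78.2% of peaks had a symbol. This matching rule was not fixed in advance. It was revised several times after values of the gene lists had been seen, once because Pln had been lost, and a lookup of older symbols was added last. The first form, span overlap alone, was therefore run as an alternative.

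A total of 26 gene lists was fixed before the data were examined. For each list, 2 values were taken, the median log2 ratio of each gene's strongest promoter peak and the median of each gene's mean over all assigned peaks. Each median was placed among 10000 random lists matched on mean signal (20 bins for promoters) or on peak number and mean signal (all peaks), for lists with at least 5 measured members. The percentile describes these 2 libraries and is not a test. Lists under the 2.5 or over the 97.5 percentile are called outside the central 95%. Named genes followed a rule set before the data were examined. It took Ythdc1, the 10 highest and 10 lowest promoter peaks and the 5 highest and 5 lowest peaks outside promoters in the upper part of mean signal (1 per gene, no predicted genes), and up to 4 members of each list with the largest difference at their promoter. Anything named outside it is said to have been chosen after its values were seen.

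The steps were tested on simulated data. With 200 of 58076 peaks changed, all drawn from the upper part of mean signal, the 2-fold rule recovered 100% of 3-fold and 3% of 1.5-fold changes. Over all peaks 95.9% of intervals held the true ratio. Recovery was not simulated in the lower part of mean signal, where 2998 peaks of the data were at least 2-fold higher and 4665 lower. Of 1000 random lists of 15 genes drawn from 13195, 6.3% fell outside the central 95%, and 98.7% of lists shifted by 0.4 on the log2 scale lay over the 97.5 percentile. Alternatives covered the scaling of the libraries (median centring, TMM factors from edgeR 4.0.16 in R 4.3.3, a loess trend with span 0.3, the authors' RPM), the peak set, the threshold, the pseudocount, the promoter distance and the gene names. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.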

Results

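Accessibility was profiled in the hearts of mice 15 days of age, to ask how cardiac deletion of Ythdc1, which encodes a nuclear reader of N6-methyladenosine in RNA, affects open chromatin. There was 1 library from floxed control mice and 1 from knockout mice, with 6755590 and 6466537 counts in 58076 peaks. All differences below are between these 2 libraries, have no replicate check, and carry intervals for counting error only.

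The single peak assigned to Ythdc1 (ENSMUSG00000035851), at its promoter on chromosome 5 from 86803786 to 86804858 (GRCm38), held 358 counts in the control and 314 in the knockout. The log2 ratio was -0.13, and the ratio of 0.916 had a 95% interval of 0.785 to 1.07. A promoter peak need not lie in the deleted part of the gene, so this value does not check the genotype labels.

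Ankrd1, a cardiac ankyrin repeat protein gene induced by stretch, had the highest ratio among promoter peaks that had a matched symbol and lay in the upper part of promoter signal, from 181 to 507 counts (chromosome 19, 36119760 to 36120664, log2 ratio 1.55, ratio 2.92, interval 2.46 to 3.49). A peak just downstream of the same gene (36110149 to 36111870) went from 332 to 1814 counts, a ratio of 5.70 (5.08 to 6.44). The next promoters under this rule were those of Synpo (2.89), Adipor2 (2.40), Sorbs3 (2.34), Tns1 (2.32), Syt11 (2.28), Atcay (2.28), Osmr, a receptor of oncostatin M (2.26), Fkbp5, a co-chaperone of steroid receptors (2.24) and Jade2 (2.22). Outside promoters, under the same rule, the highest ratios after Ankrd1 were at peaks assigned to Zbtb16 (4.60), Lsm14a (4.20), Sorbs2os (4.04) and Sdc4, whose peak went from 37 to 143 counts. The peaks of Zbtb16, Lsm14a, Sorbs2os and Sdc4 were called in the knockout library alone, as were the promoter peaks of Synpo and Atcay. Such peaks are selected for a high count in that library.

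The lowest promoter ratios under the same rule were at Nmrk2, a nicotinamide riboside kinase gene of muscle (302 against 127 counts, ratio 0.440, 0.354 to 0.542), Tuba8 (0.466), H2-Q7 (0.489), Trappc12 (0.492), Schip1 (0.493), Wdr59 (0.498), Myh7 (0.499), Ehmt1 (0.502), Kcnh2 (0.514) and Tdrkh (0.529). H2-Q7 belongs to a family of near-identical genes, so its reads are uncertain. Outside promoters, the lowest under the rule was a distal peak assigned to Tnfsf13b on chromosome 8 (10040798 to 10041416), with 169 counts in the control and 13 in the knockout, a ratio of 0.0832 (0.0419 to 0.141). It was followed by peaks assigned to Adrb1, the cardiac beta-1 adrenergic receptor gene (0.228), Smad1 (0.242), Cables1 (0.243) and Ppm1b (0.249). The Smad1 peak lay in an intron. The others were distal, with distances to the transcription start of -53001 bp (Adrb1), -23593 bp (Cables1) and -82760 bp (Ppm1b). The peaks assigned to Tnfsf13b, Adrb1, Smad1, Cables1 and Ppm1b were all called in the control library alone. So were the promoter peaks of Nmrk2, Myh7 and Kcnh2.

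Of the 58076 peaks, 3537 (6.09%) were at least 2-fold higher in the knockout and 5201 (8.96%) at least 2-fold lower, and the median log2 ratio was -0.05 (SD 0.71 over peaks). Counting error alone gave on average 126 higher and 136 lower peaks. The excess of lower peaks depended on scaling and signal. Higher peaks made up 40.5% of those that differed at least 2-fold, but 24.6% on the authors' RPM scale, 68.6% after removal of a loess trend, and 50.1% in the upper part of mean signal (539 higher, 536 lower). The RPM scale shifts each log2 ratio by about -0.17 relative to the scaling used here, so directions are relative to the peaks as a whole. The lowest decile of mean signal had a median log2 ratio of -0.64.

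**Figure D1:**
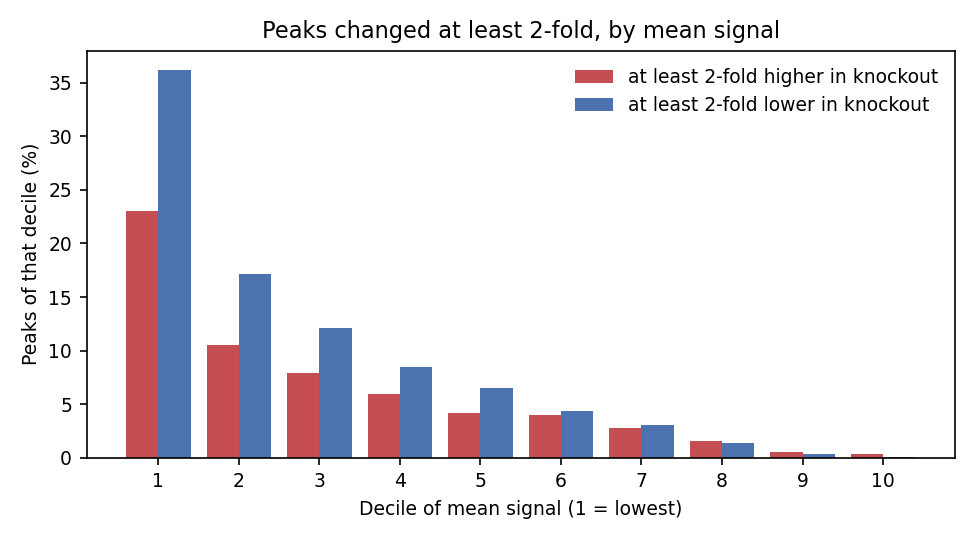
Share of peaks at least 2-fold higher or lower in the knockout library (y axis, percent) in each decile of peaks by mean signal (x axis). In the lowest decile 1337 peaks were higher and 2101 lower, and in the highest decile 23 were higher and 5 lower.

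The 2-fold counts also depended on peak calling. The authors called 48842 peaks in the control and 41191 in the knockout. Of the merged set, 31957 were called in both, 16885 in the control alone and 9234 in the knockout alone. Among peaks called in both, 98.1% lay within 2-fold (272 higher, 327 lower), against 71.1% of peaks called in the control alone and 64.7% of those called in the knockout alone. Peaks called in the control alone had 2 higher and 4874 lower, and those called in the knockout alone 3263 and 0. A difference of this direction is built in, since such peaks are selected for a high count in 1 library.

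Promoters differed less than other regions. Of 19366 promoter peaks, 522 were at least 2-fold higher and 555 lower, 5.56% in all, against 19.9% of 19107 intragenic and 20.9% of 14493 intergenic peaks. Promoter peaks were also stronger, with a median of 21 CPM against 7.26 and 6.69. Within the upper part of mean signal the shares were 1.26%, 6.42% and 6.24%, with signal still unequal at medians of 28.8, 14.3 and 14.6 CPM. Median log2 ratios of autosomes ranged from -0.10 on chromosome 13 to -0.0024 on chromosome 11. The median was -0.08 on X (909 peaks), 0.30 on Y (26 peaks, 2504 counts in the control and 3003 in the knockout) and 0.18 on unplaced sequences (73 peaks). The sex of the animals was not among the labels used here.

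Genes of calcium handling and ion channels had the lowest promoter median among lists with at least 5 measured members. Of 16 members with a promoter peak, 14 lay below 0 and 2 above, with none past 2-fold, and their median log2 ratio of -0.41 was below all 10000 matched random lists. The largest differences were at Kcnh2 (-0.96), Gja1, the connexin of ventricular gap junctions (-0.81), Pln, the inhibitor of the calcium pump (-0.54) and Kcnip2 (-0.53). Over all their peaks, 19 members had a median of -0.27, at percentile 0.51. Sarcomere and Z-disc genes had a promoter median of -0.01 (20 members, percentile 60.0), 9 of them above 0, with Actc1 at -0.80, Tnni3 at -0.52, Myoz2 at -0.38 and Myom2 at 0.35, but with promoters defined within 3 kb this median was -0.18 over 21 members, at percentile 0.68.

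Fetal and stress genes of the heart were split. Acta1, skeletal alpha-actin (18 and 66 counts, log2 ratio 1.91), Tnni1 (33 and 110, 1.78) and Ankrd1 (1.55) were at least 2-fold higher, whereas Myh7, the fetal myosin heavy chain, was lower, with 281 and 134 counts. The promoter median of 9 members was 0.05, at percentile 73.2. This value depended on the choice of peaks and on naming. The median was 0.45 (percentile 99.97) as a mean over each gene's promoter peaks, 0.36 (99.94) with promoters within 3 kb, and 0.33 over 8 members (99.4) with the first form of the name matching. Over all peaks the median of 10 members was 0.46, at percentile 99.99, but 0.18 (91.5) among peaks called in both libraries and 0.24 over 6 members (90.5) outside promoters, both inside the central 95%.

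Peaks near Nppa, the atrial natriuretic peptide gene, were chosen after their values were seen, because the table assigns them to an identifier (ENSMUSG00000086806) that had no symbol match. The peak on chromosome 4 from 148003002 to 148005062 lay beyond the Nppa span that ends at 148002074 and covered the low-coordinate end, at 148004259, of the neighbouring chloride channel gene Clcn6. It went from 168 to 1067 counts (log2 ratio 2.73, ratio 6.62, interval 5.63 to 7.85). The next peak, from 148005736 to 148006213 and within the Clcn6 span, went from 41 to 260 counts (6.56, 4.75 to 9.45). Both were called in the knockout library alone, as was the Nppb peak from 147979651 below. Of the peaks assigned to the neighbouring Nppb, the promoter peak had 328 and 305 counts (ratio 0.972, 0.828 to 1.14). Of the other 4, the peak from 147987795 had 474 and 808 counts (1.78, 1.59 to 2.00), that from 147979651 had 26 and 58 (2.31, 1.44 to 3.86), that from 147969404 had 54 and 77 (1.49, 1.04 to 2.15), and that from 147963528 had 289 and 233 (0.843, 0.706 to 1.004, an interval that holds 1). Also chosen after their values were seen were peaks upstream of Myh7, the strongest of which (chromosome 14, 55003748 to 55005134) had 2121 counts in the control and 915 in the knockout, and both promoter peaks of Mir133a-2, a muscle microRNA gene. The stronger of these had 2723 and 1641 counts (log2 ratio -0.67) and the weaker 736 and 321 (-1.13). The weaker was called in the control library alone.

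**Figure D2:**
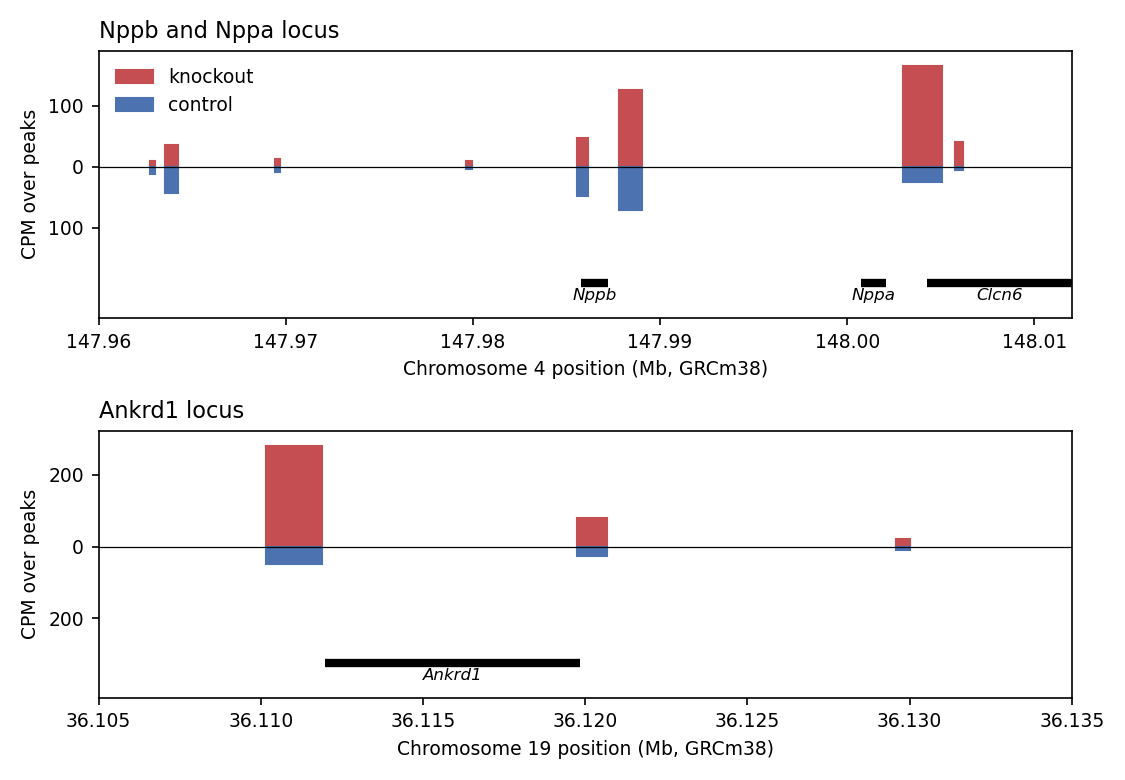
CPM over peaks (y axis) in the knockout library (upward bars) and the control library (downward bars) along the Nppb and Nppa locus and the Ankrd1 locus (x axis, Mb on GRCm38), with gene spans in black. Bar width is the peak's width. The peak between Nppa and Clcn6, which overlaps Clcn6, reached 165 CPM in the knockout and 24.9 in the control, and the peak downstream of Ankrd1 281 and 49.1.

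Genes of extracellular matrix and fibrosis had a promoter median of 0.18 (14 of 17 above 0, percentile 98.5), with Timp1 at 1.10, Col1a2 at 0.83, Lox at 0.75 and Mmp2 at -0.85. Over all peaks the median of 18 members was 0.36, at percentile 99.98, but only 0.12 and inside the central 95% when peaks called in both libraries were used. Endothelial markers had a promoter median of 0.22 (10 of 15 above 0, percentile 99.0), with Vwf at 0.81 and Sox18 at 0.79, and an all-peak median of 0.16 (percentile 97.8). As a mean over promoter peaks the promoter median was 0.099 (percentile 87.6), and the all-peak median lay at percentile 97.3 with a loess trend removed and 91.4 outside promoters, all inside the central 95%. Mural cell markers had a promoter median of 0.31 over 7 members (percentile 97.8), with Tagln at 0.83 and Kcnj8 at -0.64, and an all-peak median of -0.06 (percentile 53.6). With the first form of the name matching the promoter medians of endothelial and mural markers lay inside the central 95%, at percentiles 97.2 and 97.4, and the mural median did so also as a mean over promoter peaks (97.4), with promoters within 3 kb (95.5) and on the RPM scale (97.485). On the RPM scale the matrix and endothelial promoter medians were 0.01 and 0.05. Fibroblast markers had an all-peak median of 0.17 (percentile 92.0).

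Cell cycle genes had log2 ratios below 0 at 18 of 19 promoters, 1 of them past 2-fold, with a median of -0.22 (percentile 0.74). Plk1, a mitotic kinase gene, had 182 and 81 counts (-1.10), and Bub1 (-0.66) and E2f1 (-0.57) followed. Their all-peak median was -0.20 (percentile 1.31), and the 5 members with peaks outside promoters had a median of 0.10 over those peaks (percentile 69.8). Immediate early genes had an all-peak median of -0.12 (percentile 2.12) and a promoter median of -0.10 (percentile 6.34). Over all peaks 6 of 14 members lay above 0 and the mean, 0.015, had the opposite sign to the median, which was inside the central 95% outside promoters (percentile 9.02) and among peaks called in both libraries (4.87). Epithelial and lung markers had 5 measured members with an all-peak median of 0.46 (percentile 98.0), inside the central 95% with a loess trend removed (96.8) and outside promoters (96.9). In all, 5 of 17 lists at promoters and 7 of 21 over all peaks lay outside the central 95%. Of lists of independently drawn genes, 5% would be so. Members of these lists may vary together and the 2 measures share peaks, so 5% is not the rate to set against a genotype difference.

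The remaining lists with enough members lay inside the central 95% for each measure they had. Over all peaks alone, the percentile was 84.6 for myeloid, 5.22 for skeletal muscle and 39.5 for adipocyte markers. The promoter percentile was 20.4 for cardiac transcription factors, 16.9 for fatty acid oxidation and mitochondria, 65.7 for p53 targets, 3.52 for interferon and inflammation genes, 17.0 for the m6A writers, readers and erasers, 22.4 for splicing regulators, 35.1 for developmental regulators of other lineages and 76.9 for housekeeping genes, whose median was 0.04. As a mean over promoter peaks the m6A list had a median of 0.13 (percentile 98.1), against -0.08 for the strongest peak, whose mean over members was 0.06, and with a loess trend removed the interferon and inflammation list lay at percentile 1.51 (median -0.31), both outside the central 95%.

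**Figure D3:**
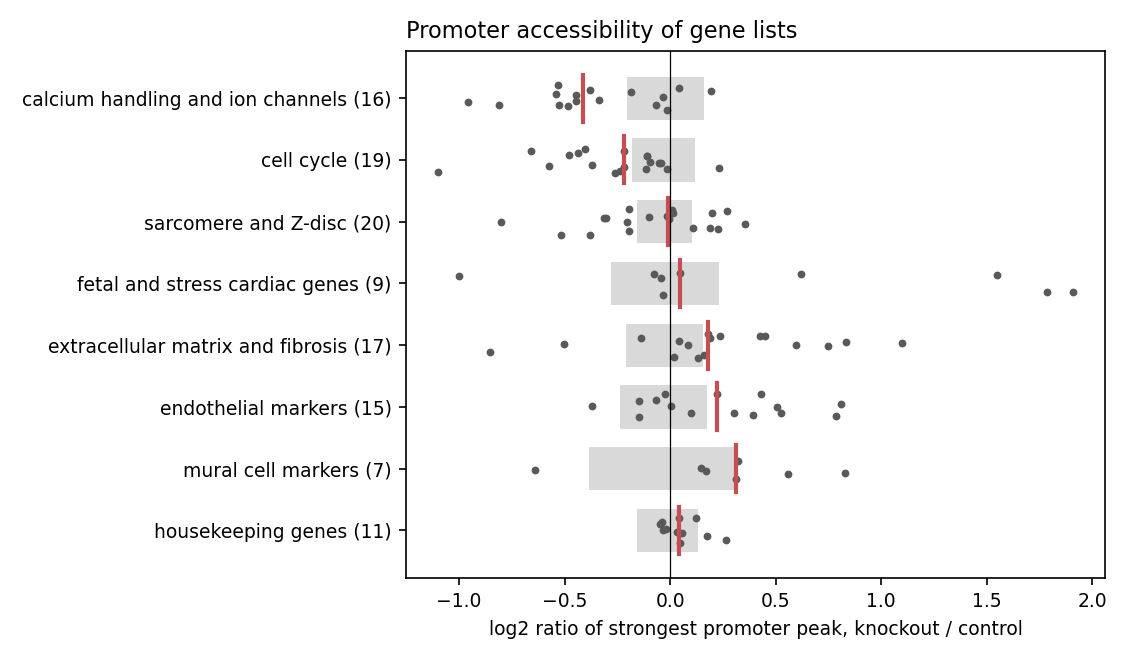
Log2 ratio (x axis) of the strongest promoter peak of each member (points) of 8 gene lists (y axis, measured members in parentheses). Red bars are medians, and grey bands hold the central 95% of medians of matched random lists. The calcium handling median of -0.41 lies below its band and the housekeeping median of 0.04 within it.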

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

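The choices of RPM scale, peaks called in both libraries, peaks over 5000 counts and first form of the name matching were added after the data had been seen; the cause of none of the shifts was tested. The median log2 ratio of all peaks, -0.05, became 0 by construction with median centring, 0.00040 with TMM, 0.010 with loess, -0.046 with a 10 times larger pseudocount, -0.22 on the RPM scale, 0.0021 in the upper part of signal, 0.0091 for peaks called in both libraries and -0.040 without peaks over 5000 counts. Peaks at least 2-fold lower numbered 2388 with loess, and 2326 were higher on the RPM scale. The upper part of signal held 539 higher and 536 lower, peaks called in both libraries 272 and 327, and the 1.5-fold rule gave 8381 and 11642. Promoters within 3 kb differed in 7.82% of cases. With fold enrichment of at least 10, 16957 peaks were shared, 11103 were of the control alone and 4473 of the knockout alone.

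At promoters, endothelial medians left the outer range as a mean over promoter peaks (0.099) and with the first name matching (0.16), and mural medians as a mean (0.31), within 3 kb (0.24), on the RPM scale (0.14) and with the first name matching (0.31). Over all peaks, endothelial markers did so with loess (0.23), outside promoters (0.16) and with the first name matching (0.16), epithelial markers with loess (0.47) and outside promoters (0.46), stress genes outside promoters (0.24) and among peaks called in both (0.18), matrix genes among peaks called in both (0.12), and immediate early genes outside promoters (-0.19) and among peaks called in both (-0.070). The cell cycle median was 0.10 outside promoters, over 5 of 20 members and at percentile 69.8, so that the sign differs in a smaller set of genes. At promoters, lists inside the central 95% moved out of it for stress genes (0.45 as a mean, 0.36 within 3 kb, 0.33 with the first name matching), m6A genes as a mean (0.13), interferon genes with loess (-0.31) and sarcomere genes within 3 kb (-0.18). Calcium handling genes stayed in the outer range under each alternative run, at promoters and over all peaks. Of 150 alternative values of the 30 named peaks, 2 moved beyond their counting interval, both on the RPM scale; these peaks were chosen for large ratios, and the largest change of log2 was 0.38, so their signs were not put to a test. A stricter significance level and another overlap rule were not run, since the table used here holds neither a p-value nor the original intervals. The weakest peaks, with a median of 25 counts in the control library in the lowest decile, limit what single ratios can show.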

Other observations

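Of the tests in this part, only those of the glucocorticoid, SRF and YAP lists were set before their result was seen. Those on cell composition, scaling and peak calling were chosen after it, and the alternatives added for the 3 lists were too. Several genes had many peaks higher in the knockout, and were chosen after their values were seen. Fkbp5 had 8 of 8 peaks above 0 and 6 at least 2-fold higher, Ddit4 11 of 12 and 6, and Tns1 42 of 48 and 7. Lower peaks gathered at Lrtm1 (5 of 5 at least 2-fold lower), Camta1 (8 of 21) and Vldlr (6 of 13). Among 1569 GO terms of the deposited table, 1 lay above and 3 lay below limits from 100 permutations, which do not keep the correlation between neighbouring genes. Extracellular matrix (202 genes, median 0.06) was above, and DNA repair (271, -0.10), centriole (101, -0.14) and myofibril (36, -0.38) were below.

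Fkbp5, Zbtb16 and Ddit4 are known targets of the glucocorticoid receptor, and their peaks prompted a list of 20 other induced genes, without these 3. Their all-peak median was 0.31 over 18 members, 14 above 0, at percentile 100 of matched random lists, and the promoter percentile was 99.6. At promoters 13 of 18 members lay above 0. Angptl4 (promoter 0.75), Mt2 (0.79) and Hif3a (0.48) were among the higher members and Irs2 (-0.42) and Nfil3 (-0.25) among the lower. Per1 (-0.03) and Tsc22d3 (-0.08) lay slightly below 0 at their promoters. The members named here were chosen after their values were seen. The percentile was 99.97 with loess, 99.87 outside promoters (10 members), 99.4 among peaks called in both libraries and 99.98 with the first form of the name matching. These values are consistent with higher glucocorticoid signalling in the knockout heart, as a hypothesis from 1 library per genotype. Receptor binding, hormone levels and replicate hearts, which would bear on it directly, were not analysed here. Stress or handling of the animals before dissection may give the same pattern, as may a change in cell composition. Neither was tested for this list.

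The peaks at Ankrd1, Tns1, Mical2 and Synpo prompted lists of other targets of SRF with MRTF and of YAP with TEAD, both of which act downstream of tension. Their all-peak medians lay at percentiles 85.2 and 35.3, so neither met the bound set beforehand, the upper end of the central 95%. The SRF list reached 99.7 at promoters and 99.45 among peaks called in both libraries, measures that were not the one set beforehand. It lay at 92.35 with loess and 89.1 with the first form of the name matching. Outside promoters it lay at 33.4, with a median of -0.12 over 12 members. In all, 3 such lists were tried.

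Calcium handling genes lay low, while matrix, endothelial and stress genes lay high, and a lower share of cardiomyocyte nuclei in the knockout library may account for part of this. At the main settings, other cardiomyocyte lists (sarcomere, transcription factors, fatty acid oxidation) and the fibroblast list lay inside the central 95%. With promoters within 3 kb the sarcomere median was outside it (-0.18, percentile 0.68), and it stayed inside under the other promoter settings run. The GO term myofibril (36 genes, median -0.38) lay below its permutation limit. Whether the sarcomere and calcium handling lists are equally particular to cardiomyocytes was not measured. If they are, a lower share would lower sarcomere promoters along with calcium handling promoters, the list with the lowest median. The difference of their medians was 0.40 (0.0079 to 0.53 from resampling genes), which in a first form of the test argued against it, but with promoters within 3 kb it was 0.12 (-0.13 to 0.43) and over all peaks 0.20 (-0.038 to 0.48), both added after that first interval was seen. The stress list's median of 0.46 (-0.044 to 0.73) and the endothelial minus mural difference of 0.22 (-0.060 to 0.65) decide nothing either. All these intervals cover the choice of genes only, and cell shares were not measured in the 1 library per genotype. A change in cell composition and a change within cardiomyocytes therefore cannot be told apart here.

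The excess of lower over higher peaks may come from scaling or peak calling. A first form of the scaling test used median centring alone, which left higher peaks at 45.9%. Over all scalings tried the share ran from 24.6% to 68.6%, on both sides of an even split, so the scaling cannot be told apart from a true excess. In the upper part of signal it was 50.1% (47.1 to 53.2), which peak calling near the threshold would give, as would an excess limited to weak peaks. The peak with the most counts in the knockout, on chromosome 17 from 39843002 to 39846841, was chosen after its values were seen. It had 34743 counts in the control and 56560 in the knockout. Without peaks over 5000 counts in either library, 3630 peaks were higher and 5059 lower. Higher peaks then made up 41.8%, against 40.5% with all peaks.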
